A study of Aedes aegypti with 6 samples.

How the data were processed

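Whole bodies of Aedes aegypti larvae and adults from 3 locations were pooled, 10 mosquitoes per pool, and 1 library per stage and location was sequenced, 6 in all. Per the labels' protocols, total RNA was isolated with a column kit and libraries were sequenced as paired ends of 150 bases to 20000000 reads, while the deposited gene tables account for 42123346 to 59749630, so whether they count single reads or pairs is unsure. Per the submitters' processing notes, FastQC, cutadapt, fastp, STAR and edgeR were used, with no versions given. The genome build and annotation are not given in the sources used here. Nothing says how many breeding sites gave the mosquitoes of a pool. With 1 pool per stage and location, p-values of the stage test measure only the spread between these pools of different locations. In the location tests the spread is how far location differences depart between the stages. No p-value measures the spread between pools of 1 stage and location.

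The deposited gene tables hold counts, not normalized, per gene in 3 columns (both strands together, forward and reverse), after 4 summary rows for reads not aligned, aligned to several places, in no gene or in several genes. The 4 rows were left out of all tests, and their shares are given in the report. The deposited junction tables hold counts of uniquely mapped and of multiply mapped reads per intron, with its position, strand and whether it was annotated. The forward column over the reverse column was 1.15 to 1.24 in all 6 libraries, under the limit of 3 that was set, so the column for both strands was used. Reads from overlapping genes on opposite strands can then not be told apart, and reads at several places were counted for no gene, which lowers the counts of genes with near-identical copies.

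Of 19804 gene identifiers, 10912 had no count in any library and 0 matched the reference table of assembly AaegL5.0. The 27 gene lists fixed for set tests therefore had no members, the set tests were not run, and no gene is given a name. For junctions, the RefSeq gene that alone contains the intron was looked up by position. Of the 15077 annotated introns on chromosomes 1 to 3, 99.97% lay inside a RefSeq gene, against 55.97% after shifting them by 100000 bp and 53.55% by 1000000 bp, and on that basis the RefSeq table was used for symbols and gene order only. Of 15579 annotated junctions, 92.8% lay in exactly 1 gene. Per RefSeq gene, the uniquely mapped reads of these junctions were summed, and their CPM is relative to all such reads in RefSeq genes.

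Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr on stage, glmQLFit and glmQLFTest) and Benjamini-Hochberg adjusted p under 0.05, larvae against adults with 4 residual degrees of freedom, and each pair of locations as the mean over both stages with stage as a covariate and 2 residual degrees of freedom. Junctions with at least 10 unique reads over the libraries and reads in at least 2 were grouped by a shared intron start or end and tested with diffSpliceDGE. Within a group, the share given is that of the junction that rose most in adults. DESeq2 1.42.0 and limma 3.58.1 were loaded, and DESeq2's Wald test served as an alternative, with 26 genes left without an adjusted p in the stage test. Python 3.11.15 with scipy 1.17.1 gave the exact permutation tests and Clopper-Pearson intervals at 95%. A fold against a stage with no counts used 3 counts over its 3 libraries as the floor, and intervals and floors cover counting error only, since reads from one amplified fragment are not independent.

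The rules for named genes were set before the data were examined. Without names, they give at most 2 identifiers per direction, the largest log2 fold changes among called genes with the same direction in all 3 locations and at least 10 CPM in the higher stage. For locations, they give called genes with the same sign in larvae and adults or, where nothing passed, the 2 with the smallest p in each direction. For junctions, they give the 5 groups with the smallest p. The test on RefSeq genes, its 6 genes per direction, the runs of neighbours, the exon shares, an F test over the 3 locations and AAEL006259 were chosen after seeing the data, as were LOC5568132 and LOC5576127. Alternatives were DESeq2 size factors, library totals, DESeq2's test, no low-count filter, the forward column, a test against a 2-fold change, at least 30 reads or annotated junctions only, location number as a block, and each library left out.

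The spread of the genes' forward-strand shares measured how far reads depart from independent counting. For genes with 20 to 100 reads, a window chosen after looking at several others, its variance over the binomial value was 25.6, 3.32 and 14.4 in the larvae of locations 1, 2 and 3 and 8.59, 11.7 and 3.88 in the adults, where independent reads from genes alike in strand share give about 1. Counts divided by this ratio were an added alternative. On simulated counts for the 5030 genes with 200 genes changed, the stage test recovered 22% of 8-fold and 69% of 64-fold changes with 4 false calls, and the test of locations 1 and 2 recovered 13% and 66% with 5 false calls, so changes under 8-fold are mostly missed. The junction test was simulated on 620 groups under 3 noise settings, the mildest of which was written after earlier, stricter forms had recovered none of 60 switches. With separate noise per junction it recovered 10% of 16-fold and 53.3% of 256-fold switches, with noise shared within a group at its median dispersion 0% and 0%, and at its smallest dispersion 10% and 76.7%, with 0 false calls in each. A first form with 1 changed junction per group had recovered none and was replaced. In unchanged groups the median p was 0.406, 0.701 and 0.623 under the 3 settings, on either side of 0.5, and the recovery in real data is unknown.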

Results

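Whole-body RNA of the mosquito Aedes aegypti was sequenced at 2 developmental stages, larva and adult, from 3 collection locations in Eastern India that the labels name K1 (location 1), K3 (location 2) and C (location 3). Each of the 6 libraries was made from a pool of 10 mosquitoes, so each stage had 3 libraries and each location had 1 larval and 1 adult library. The sex and feeding state of the adults and the age of the larvae were not given in the sources used here. The gene tables accounted for 42123346 to 59749630 reads per library. Reads counted for a single gene numbered 13758058, 12049243 and 18328454 in the larvae of locations 1, 2 and 3, and 10450701, 3271618 and 4360094 in the adults. At the smallest of these totals, 3 counts were 9.17e-05% of the gene counts, and at the largest 1.64e-05%.

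The 2 stages differed in how their reads were placed on the genome. Reads that aligned to several places made up 45.8% ± 14.3 (SD, n = 3) of the adult reads and 13.2% ± 2.64 (SD, n = 3) of the larval reads. Reads that did not align made up 35.6% ± 11.6 (SD, n = 3) in adults and 56.7% ± 1.76 (SD, n = 3) in larvae. Reads counted for a gene were 12.1% ± 5.43 (SD, n = 3) in adults and 27.9% ± 2.58 (SD, n = 3) in larvae. In all 3 measures every adult library lay on one side of every larval library, for which a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The number of genes with at least 1 count was 4856 ± 1355 (SD, n = 3) in adults and 6385 ± 1352 (SD, n = 3) in larvae, which did not separate the stages (exact permutation p = 0.3).

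**Figure D1:**
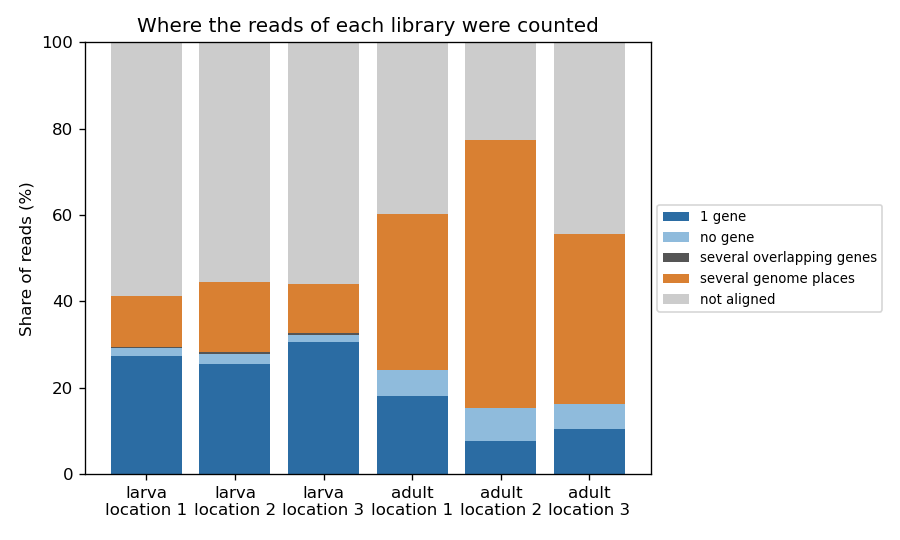
Stacked bars give, for each of the 6 libraries on the horizontal axis, the percentage of reads counted for 1 gene, for no gene, for several overlapping genes, for several genome places, or not aligned. The orange part is 11.8%, 16.2% and 11.5% in the larvae of locations 1, 2 and 3, and 36.0%, 62.2% and 39.3% in the adults.

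Adults and larvae differed in many genes, and many of the called genes were counted at 1 stage only. Of 5030 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 337 were higher in larvae and 158 were higher in adults. Of the 337, 142 had no count in any adult library, and of the 158, 40 had no count in any larval library. Each adult library held fewer gene counts than each larval library, which can leave more genes without a count in adults. Gene counts alone did not set detection. The larvae of location 1 had 5117 genes with a count, and the adults of locations 1 and 3 had 5459 and 5805. Spread over the 3 libraries of a stage, 3 counts were 0.179 per 1000000 in adults and 0.0641 in larvae. For 337 of the 337 genes higher in larvae, no location had the higher value in adults, where equal values at both stages also pass. For 157 of the 158 genes higher in adults, the adult value was the higher one in all 3 locations. The genes were called on these same libraries, so this adds no separate support. Among called genes with more than 3 counts at both stages, the median ratio of stage means was 13.3 for 172 genes higher in larvae and 11.7 for 110 genes higher in adults. The genes higher in larvae held 17.9% of the mean larval CPM (counts per 1000000, scaled by TMM) of the tested genes, and those higher in adults held 20.9% of the mean adult CPM. The adult share includes 107909 CPM of AAEL006259 alone.

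The files give gene identifiers without names, and none of them matched the reference table, so few are named here. AAEL017262 was at 3006 ± 1199 CPM (SD, n = 3) in adults and had 0 counts in the 3 larval libraries. Against the floor of 3 counts over the 3 larval libraries it was at least 46864-fold higher in adults (log2 fold change 17.96, SE 0.94, edgeR adjusted p = 0.000284). AAEL019798 was at 646 ± 258 CPM (SD, n = 3) in adults and also at 0 in larvae, at least 10075-fold higher in adults (edgeR adjusted p = 0.000324). In the other direction, AAEL004239 was at 1897 ± 756 CPM (SD, n = 3) in larvae and 0 in adults, at least 10575-fold lower in adults (log2 fold change -17.29, SE 1.03, edgeR adjusted p = 0.000324). AAEL000896 was at 4844 ± 4843 CPM (SD, n = 3) in larvae, from 349 at location 3 to 9973 at location 2, and 0 in adults, at least 27005-fold lower there (edgeR adjusted p = 0.00255). These bounds, and those for junction reads below, cover counting error only, so the true bounds may be lower. With counts divided by the strand-variance ratio, the fitted log2 fold change was 15.04 for AAEL017262 and 12.79 for AAEL019798. It was -14.16 for AAEL004239 and -15.51 for AAEL000896. One further gene, AAEL006259, was singled out after its values were seen because it took the most counts in each adult library. It held 12.3%, 11.9% and 7.12% of the gene counts in the adults of locations 1, 2 and 3, and 0.00532%, 0.0280% and 0.0134% in the larvae. Its mean was 107909 ± 32011 CPM (SD, n = 3) in adults and 169 ± 154 CPM (SD, n = 3) in larvae, a ratio of 640 (edgeR adjusted p = 0.000495).

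The counts of called genes moved with the test and the libraries used. The genes higher in adults numbered 353 with DESeq2, 294 with no low-count filter and 278 with counts divided by the strand-variance ratio. The genes higher in larvae numbered 619, 517 and 369 in the same order. With no filter 8892 genes were tested and with divided counts 2132, against 5030, so their counts are not like for like. Without larva replicate 1, adult replicate 1, larva replicate 3 or adult replicate 3, the genes higher in adults numbered 75, 87, 80 and 82. Without larva replicate 1, adult replicate 1 or adult replicate 3, the genes higher in larvae numbered 201, 214 and 204.

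Reads across annotated introns gave the same comparison for genes that the RefSeq table of assembly AaegL5.0 lists by LOC symbol. Of 2534 such genes tested, 117 had more junction reads in larvae and 55 had more in adults. No location had the opposite direction for any of the 172, where equal values at both stages also pass for the 117. Of the 117, 51 had no junction read in any adult library, and of the 55, 17 had none in any larval library. Depth differed here too, since 3 junction reads were 0.503 CPM over the adult libraries and 0.188 CPM over the larval ones. All 12 genes named in the next sentences are protein-coding. LOC5579954 on chromosome 1 had the largest fitted change, with 17073 ± 7208 CPM of junction reads (SD, n = 3) in larvae and 0 in adults, at least 33939-fold lower in adults (edgeR adjusted p = 3.4e-05). Its neighbour LOC5579955 was at 2372 ± 370 CPM (SD, n = 3) in larvae and 0 in adults, at least 4715-fold lower (edgeR adjusted p = 4.77e-05). LOC5579510, also on chromosome 1, was at 1640 ± 2309 CPM (SD, n = 3), LOC5567234 on chromosome 3 at 3631 ± 3733, LOC5565356 on chromosome 2 at 937 ± 1235 and LOC5564398 on chromosome 1 at 929 ± 377 in larvae, and all 4 were at 0 in adults. The call of LOC5565356 ended in 3 of the 6 fits that left out 1 library, those without an adult library, at an adjusted p of up to 0.0617.

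In adults, LOC5577606 on chromosome 2 was at 1761 ± 1367 CPM of junction reads (SD, n = 3), with 12880 reads against 1 read in the 3 larval libraries together (edgeR adjusted p = 0.000283). LOC110677060 on chromosome 2 was at 556 ± 421 CPM (SD, n = 3), LOC5575401 on chromosome 3 at 313 ± 141, LOC5572260 on chromosome 3 at 273 ± 42.4, LOC5576459 on chromosome 1 at 251 ± 138 and LOC5571814 on chromosome 2 at 127 ± 51.8. These 5 had no junction read in larvae and were at least 2956-fold, 1663-fold, 1451-fold, 1336-fold and 675-fold higher in adults, in the same order. The share of tested genes that were called was 6.14% on chromosome 1, 6.92% on chromosome 2 and 7.10% on chromosome 3, which did not differ by Fisher's exact test (two-sided p = 0.76). Without larva replicate 1, adult replicate 1, larva replicate 3 or adult replicate 3, the genes higher in adults numbered 30, 28, 32 and 25, and those higher in larvae numbered 61, 70, 73 and 67.

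Genes called in one direction lay near each other more often than permuted calls did, though most called genes had no such neighbour. With at most 2 other protein-coding genes between them, 19 neighbouring pairs of called genes went the same way, against a mean of 4.30 and a maximum of 13 in 10000 permutations of the calls over the tested genes (p = 1e-04, the smallest these permutations can give). The pairs formed 11 runs that held 30 of the 172 called genes, and 4 of the runs had 3 or more genes. LOC5566739, LOC5566738, LOC5566737, LOC5566735 and LOC5566734 lay in 1 run on chromosome 3, where the introns counted lie between positions 159812000 and 159878685. Their larval means ran from 291 to 950 CPM of junction reads, with 45058 reads in larvae against 3 in adults. LOC5576719, LOC5576718, LOC5576717 and LOC5576712 lay on chromosome 1 with larval means from 43.9 to 342 CPM and 18 adult reads in all. In the other direction, LOC5572260, LOC5575401 and LOC5575400 were adjacent on chromosome 3, with adult means from 30.8 to 313 CPM and 0 larval reads. LOC5573903, LOC110677060, LOC23687822 and LOC110677062 lay on chromosome 2 with adult means from 15.6 to 556 CPM and 36 larval reads in all. LOC5573903 and LOC110677062 were near the threshold (edgeR adjusted p = 0.0409 and 0.043), and the call of each ended in 5 of the 6 fits that left out 1 library. The call of LOC5576717 ended in 4 of the 6, that of LOC5576719 in 2 and that of LOC5575400 in 1.

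**Figure D2:**
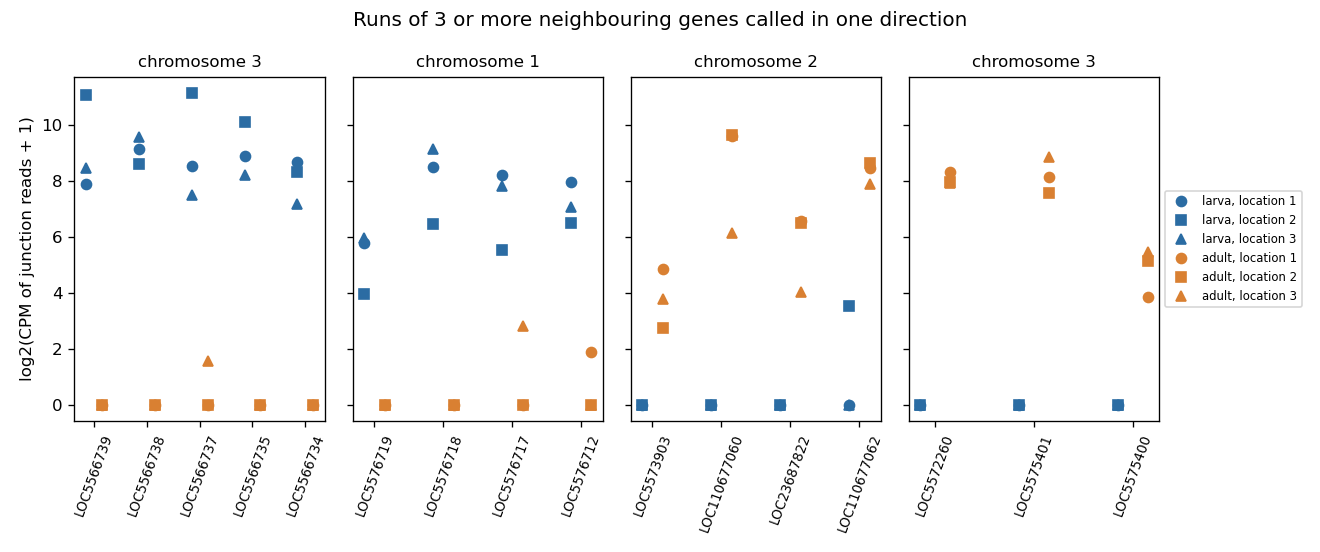
Each point is 1 library's junction reads for 1 gene, as log2(CPM + 1), for the 4 runs of 3 or more neighbouring genes, with larvae in blue, adults in orange and a marker shape per location. In the runs on the left, larval means reach 950 and 342 CPM and the adult points lie at or near 0, and in the runs on the right the adult points are the higher ones.

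The stages also used different splice junctions within the same genes. Of 620 groups of junctions that share 1 intron end, 14 were called between the stages (edgeR's diffSpliceDGE, adjusted p under 0.05), and these lay in 11 RefSeq genes. Not every called group split cleanly by stage. The junction given for LOC5569815 took 0 of 30, 66 of 66 and 4 of 31 reads in the adults of locations 1, 2 and 3. That of LOC5573031 took 75 of 111, 5 of 5 and 16 of 253. The groups of LOC23687432 and LOC5574096 had no read in the adults of location 2, and that of LOC5574096 had 0, 1 and 33 larval reads. In LOC5574015, on the minus strand of chromosome 1, junctions frame an exon of 401 bp at positions 54684457 to 54684857. The junction at its left end took 78.4% ± 14.8 (SD, n = 3) of its group's adult reads and 1.16% ± 0.388 (SD, n = 3) of the larval ones (adjusted p = 7.04e-06). The junction at its right end took 87.7% ± 7.59 (SD, n = 3) and 26.0% ± 5.07 (SD, n = 3) (adjusted p = 0.0374). In larvae the right junction had 902, 1030 and 1712 reads and the left one 26, 36 and 59, so most of the larval reads at the right end cannot be counted as inclusion of this exon. In LOC5576127, on the minus strand of chromosome 1, an exon of 57 bp at positions 305086486 to 305086542 was used mostly in adults. The junction at its left end took 397 of 407 and 19 of 19 of its group's reads in the adults of locations 1 and 3, and 0 of 39, 2 of 77 and 0 of 74 in larvae (adjusted p = 0.00531). The junction at its right end took 413 of 423 and 23 of 30 in those adults, and 0 of 47, 2 of 116 and 0 of 93 in larvae (adjusted p = 0.00657), and the adults of location 2 had no read at either end. In LOC5568131, on the plus strand of chromosome 2, the intron from 133384128 to 133395489 took 95.5% ± 5.52 (SD, n = 3) of its group's adult reads and 0 of 58, 42 and 33 larval reads (adjusted p = 3.25e-05). In the adults of location 2 it took 49 of 55. After dividing by that library's strand-variance ratio, 4 of 5 remain, with an exact 95% interval of 28.4 to 99.5%. The larval reads of LOC5568131 and the reads of LOC5576127 were not scaled in this way. In LOC5568132, on the same strand of chromosome 2, the intron from 133263138 to 133284732 took 97.4%, 93.3% and 94.4% in the adults of locations 1, 2 and 3 and 6.11% ± 2.55 (SD, n = 3) in larvae (adjusted p = 0.000951).

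In LOC5580231, on the plus strand of chromosome 1, the adult libraries did not move together. An exon of 111 bp at positions 160910904 to 160911014 was included in 98.4% ± 1.60 (SD, n = 3) of the larval junction reads. It was included in 26.4% and 25.9% of the reads in the adults of locations 1 and 3, and in 98.4% of those in the adults of location 2. The skipping intron, from 160910646 to 160911526, took 181 of 6449 reads of its left-end group in the adults of location 2, a share of 2.81% (exact 95% interval 2.42 to 3.24%), against 75.6% and 78.7% at locations 1 and 3 (adjusted p = 0.000951 over all 6 libraries). In LOC5575278, on the plus strand of chromosome 3, the intron from 291066809 to 291077320 took 786 of 2708 and 70 of 302 reads in the adults of locations 1 and 3. It took 0 of 44 in the adults of location 2 and 0.0443% ± 0.0767 (SD, n = 3) in larvae (adjusted p = 0.000532). After dividing reads by that library's strand-variance ratio, 0 of 4 remain in the adults of location 2, with an upper 95% bound of 60.2%, so this value does not set them apart from the other adults. Without adult replicate 1, larva replicate 1, adult replicate 2 or larva replicate 3, the number of called groups was 3, 8, 9 and 9. Without adult replicate 1, the calls of LOC5575278, LOC5568132 and 1 group of LOC5580231 ended, each at an adjusted p of 0.0563, as did both groups of LOC5576127, at 0.179 and 0.379. The other group of LOC5580231 ended without larva replicate 1, at 0.0872. The group at the right end of the LOC5574015 exon ended in 5 of the 6 fits that left out 1 library, while the group at its left end kept its call in all 6.

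**Figure D3:**
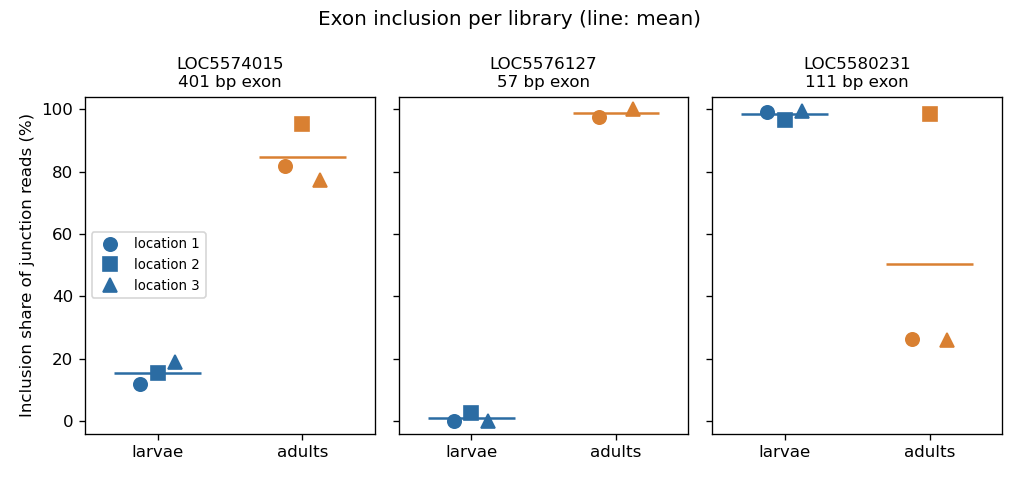
Each point is 1 library's inclusion share for 3 exons, as the mean reads of both framing junctions over that mean plus the skipping reads, in percent, with larvae in blue, adults in orange, a marker shape per location and a line at the mean. For LOC5574015 the larval points rest mostly on the right junction. The adult point of location 2 lies at 95.2% for LOC5574015 and at 98.4% for LOC5580231, and has no reads for LOC5576127.

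Between locations 2 and 3, with the stages averaged, 4 of 5030 genes passed the test, and all 4 were lower at location 3. The count was 19 with DESeq2, 25 with divided counts, 49 with no low-count filter, 9 with DESeq2 size factors, 7 with library totals and 1 with the forward column, so it does not measure how alike the locations are. AAEL021056 was at 435 CPM in larvae and 176 CPM in adults of location 2, and at 4.01 and 2.57 CPM at location 3 (log2 fold change -6.42, SE 0.93, edgeR adjusted p = 0.00984). AAEL004749 was at 1192 CPM in larvae of location 2 and 9.50 CPM in larvae of location 3, with 16 and 0 counts in the adults (log2 fold change -7.47, SE 1.23, edgeR adjusted p = 0.016). The other 2 called genes had no count in the adults of either location, so their calls rest on 1 larval library against 1. With 1 pool per stage and location, the p-values here measure no spread between pools of 1 location. The call of AAEL004749 ended without larva replicate 3 (edgeR adjusted p = 0.28), without larva replicate 2 (0.351) and with the forward column (0.146), and that of AAEL021056 ended without larva replicate 2 (0.229). Without larva replicate 2 no gene passed, while without adult replicate 2, larva replicate 3, adult replicate 3, larva replicate 1 or adult replicate 1 the count was 43, 18, 47, 20 and 24.

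Between locations 1 and 2, and between locations 1 and 3, edgeR called 0 genes, with 107 and 97 genes at an unadjusted p under 0.05, and DESeq2 called 0 and 1. Library totals gave 1 and 4, divided counts 1 and 1, and no low-count filter 21 and 25. The genes with the smallest p did not pass with the filter and TMM, and all 8 passed with no low-count filter. The unfiltered fit tested 8892 genes against 5030. It gave AAEL003398 an edgeR adjusted p of 2.86e-12 on the same counts, so its calls are not like for like and add no separate support. For locations 1 and 2 these were AAEL004749, AAEL004759, AAEL015140 and AAEL014231. The first 2 were at 1192 and 291 CPM in larvae of location 2 against 87.4 and 2.07 at location 1 (edgeR adjusted p = 0.392 for both). The last 2 were at 182 and 0.101 CPM in larvae of location 2 against 5030 and 14.2 at location 1 (edgeR adjusted p = 0.84 for both). In adults AAEL014231 was at 69.8 CPM at location 1 and 0 at location 2. For locations 1 and 3 the genes with the smallest p were AAEL003398, AAEL012164, AAEL021056 and AAEL023487 (edgeR adjusted p = 0.179 for all 4). AAEL003398 was at 439 CPM in adults of location 3 and 0 at location 1. AAEL012164 was at 172 CPM in larvae of location 3 and 2.07 at location 1. AAEL021056 was at 206 CPM in larvae of location 1, and AAEL023487 at 270 CPM in larvae of location 1 and 2.40 at location 3. With 1 library removed these counts rose to at most 18 and 26, from fits with 1 residual degree of freedom.

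Location differences in larvae did not go with those in adults. Across genes counted in all 4 libraries of a pair of locations, the log2 difference in larvae and that in adults had a Pearson r of -0.05 for locations 1 and 2 (2543 genes), -0.01 for locations 1 and 3 (3390 genes) and -0.07 for locations 2 and 3 (2719 genes). Among genes with at least 200 counts in each of the 4 libraries r was -0.09, -0.02 and -0.08. Genes are not independent replicates, and these values describe the libraries. Each difference is 1 library against 1 and reads depart from independent counting, so noise alone could also give values of r this small. Whether the stage difference itself depends on location could not be tested, since each combination of stage and location had 1 library.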

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

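All tests in this section were chosen after the values had been seen. The adults of location 2 had the highest share of reads at several genome places, 62.2% (exact 95% interval 62.16 to 62.19%), in rows of the gene tables that enter no comparison of genes. Library size as the source is argued against, since the lowest adult number of such reads was 2.17 times the highest larval number, although adult libraries were not larger on average. Spliced genes with similar copies are argued against as the main source, because spliced reads at several places per uniquely placed one rose 1.44-fold in adults (1.87-fold in the highest library) against 6.02-fold among all reads. Unspliced repeated sequence, ribosomal RNA left in the libraries and the stage itself stay open and were not tested.

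The skipping intron of LOC5580231 rose in adults at locations 1 and 3 and not at location 2, where adult minus larva was -1.86 and -1.32 percentage points in its 2 groups, a difference between locations that was not tested. For LOC5575278 it was -0.133 at location 2, from 0 of 44 adult and 1 of 753 larval reads, so this sign carries no information. A larval library under an adult label is argued against, since 307 of 356 genes called without this library (86.2%) lay nearer to the other adults. Of 6 junction groups called without it, 3 lay nearer to the other adults. Those that did not were the 2 groups of LOC5580231 and that of LOC5575278, the pattern in question, so they are not separate evidence on the label. Few sequenced fragments are argued against for LOC5580231, because the upper 95% bound of its skipping share was 4.46% after dividing reads by 11.7. Larval RNA as the only source of its inclusion reads is argued against, because its inclusion junction had 2.58 times the share of junction reads of the highest larval library. The inclusion reads of the other adults were not compared, so a smaller share of larval RNA in the pool stays open. The sex and tissue makeup of the adult pool and the location itself stay open as untested, and for LOC5575278 few fragments stay open too, with an upper bound of 60.2%.

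The unannotated junction with the most unique reads in any 1 library was the intron from 288426211 to 288439464 on chromosome 2. It had 13119 unique reads in the larvae of location 2, 1670 and 405 in those of locations 1 and 3, and 0 in the 3 adult libraries. It lies inside no single RefSeq gene.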

How the results depend on the processing

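The F test over locations, the RefSeq gene counts with their alternatives, and counts divided by the strand-variance ratio were chosen after seeing the data. The 5 named stage identifiers kept their direction and their call under every alternative run, 70 fits, with adjusted p up to 0.0263. Of 200 fits of named RefSeq genes, 179 kept the call and 21 lost it, with no change of direction. The genes higher in adults numbered 158, and 353 with DESeq2, 294 with no filter, 278 with divided counts and 75 to 128 with 1 library removed; the genes higher in larvae numbered 337, and 619 with DESeq2, 517 with no filter and 201 to 231 with 1 library removed. These fits did not test the same genes: 8892 with no filter, 2132 with divided counts and 5388 to 5941 with 1 library removed, against 5030. Both counts fell in every fit with 1 library removed. The cause of these changes was not tested. The median log2 fold change shifted by 0.13 with DESeq2 size factors and by -0.13 with library totals, and genes higher in larvae made up 68.1% of the calls, 63.3% and 68.0% under those, and 57.0% with divided counts. RefSeq genes numbered 25 to 56 in adults and 61 to 85 in larvae with 1 library removed. Locations 1 and 2 gave 1 gene with library totals, 21 with no filter, 1 with divided counts and 0 to 18 with 1 library removed. Locations 1 and 3 gave 4 with library totals, 1 with DESeq2, 25 with no filter, 1 with divided counts and 0 to 26. Locations 2 and 3 gave 9 with DESeq2 size factors, 7 with library totals, 19 with DESeq2, 49 with no filter, 1 with the forward column, 25 with divided counts and 0 to 47; the cause was not tested. The F test over the 3 locations called 4 genes, and 0 to 67 under the alternatives. Without larva replicate 2 the log2 fold change of AAEL004759 between locations 1 and 2 was reversed to -0.17 (up to 7.28 in the other fits), and without larva replicate 3 that of AAEL023487 between locations 1 and 3 to 1.27 (down to -8.22 in the other fits); both have no adult counts, so the left-out larvae carry the difference. Junction groups numbered 14, and 9 with at least 30 reads, which leaves 407 groups to test, 19 of 371 with annotated junctions only, and 3 to 16 with 1 library removed; of 81 fits of 9 named groups, 4 of them named after their values were seen, 66 kept the call and 15 lost it.

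Same-numbered larval and adult libraries, which share a location, had deviations from the stage means that correlated at -0.02 to 0.02, and 2 of 6 libraries correlated best with their own number, so the numbers were not treated as pairs. With the location number as a replicate block, 177 genes were higher in adults and 360 in larvae, RefSeq genes numbered 88 in adults and 169 in larvae, and junction groups 8. LOC5573903 lost its call there (adjusted p = 0.0568), as did both groups of LOC5576127 (0.0595 and 0.182).

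The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split, 1 of the 10, called 495 genes, 172 RefSeq genes and 14 junction groups, and the highest of the other splits 0 in each. The planned set tests of 27 gene lists were not run, as the lists had no members.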

Other observations

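Both tests below were chosen after the runs of neighbouring genes had been seen. The 11 runs of neighbours called in one direction included 9 with the higher value in larvae, such as LOC5579955 and LOC5579954 on chromosome 1, LOC5567235 and LOC5567234 on chromosome 3, and LOC5579048 and LOC5579049 on chromosome 3. Chance placement is argued against by the permutation of calls over the tested genes (p = 1e-04, the smallest that 10000 permutations can give). Reads of one gene assigned to its neighbour in a fixed share are argued against as the whole cause, since the ratio of neighbours' junction reads changed 3.13-fold at the median over the 3 larval libraries in 14 pairs, from 1.55-fold to 64.8-fold. The median over all pairs of genes higher in larvae was 5.60-fold, a difference that was not tested, and reads shared in part stay open. A candidate explanation is that neighbouring copies of a gene, or genes under shared regulation, change together between the stages, which was not tested, since no sequence was used here.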
